A study of Saccharomyces cerevisiae with 7 samples.

How the data were processed

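Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on 7 samples of Saccharomyces cerevisiae of the CEN.PK background, in which the histone demethylase Rph1 carried an HA epitope tag. Per the labels, cells grew in YPL (1% yeast extract, 2% peptone, 2% lactate) to log phase at an OD600 of about 1.0, and the SL samples were taken 1 h after a switch from YPL to SL, a synthetic lactate medium. The medium labels of the 2 SL samples each give a different part of the recipe, and both were treated as the same medium. Cells were fixed in 1% formaldehyde for 15 min, and 50 OD600 units went into each immunoprecipitation. Groups came from the sample titles: wild type in YPL (2 libraries), wild type after 1 h in SL (2), a ppm1 deletion strain in YPL (2) and a strain with the Rph1 substitution S412A in YPL (1). S412A stands for alanine in place of serine, at the residue of that number counted from the start of the protein.

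The deposited table gives a signal value, never negative, for 731 peaks in each of the 7 libraries. Reads were aligned with Bowtie2 to a build named sacCer2, per the submitters' processing notes, which give no version. The peak caller, the read filters, the way peaks of different libraries were merged, and any use of input DNA are not given in the sources used here. Peak positions are those of the table and were taken as counted from 1, since several peaks start at position 1. The cells were CEN.PK, whereas sacCer2 is a build of the S288C reference strain, so sequence that differs in copy number or is absent between the strains, chromosome ends in particular, can raise or lower the signal of a peak.

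In each library every value was a whole multiple of 1 step (100% of values within a tolerance of 0.001), and that step equalled 22000000 divided by a whole number between 13808893 and 34820208. The deposited signal was therefore read as reads per peak scaled to a library of 22000000. This reading comes from the values alone, what the library total counts is not given in the sources used here, and no count model was used. Under that reading the implied library totals were 15445453 and 19258711 reads for wild type in YPL, 13808893 and 20499295 for SL, 22594042 and 34820208 for the ppm1 deletion and 28785315 for S412A. The fewest implied reads in a peak were 1010, a counting error of 3.15%, and the median peak held 3276 to 7574 reads depending on the library, an error of 1.15% to 1.75%. Intervals and counting errors cover the counting of reads only, since PCR copies are not independent molecules.

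Scaling to the library total leaves in place any difference in the share of reads that fall in peaks. A library in which the immunoprecipitation worked less well shows lower values at strong peaks, and no spike-in was used here to separate that from a change of binding. No further scaling was applied in the tests reported first, since scaling over peaks would remove a change common to them. Signal per kb is the value divided by the peak width.

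Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with trend) on log2 signal with a pseudocount of 0, as no value was 0. A single fit held all 7 libraries with group as the only term, which left 3 residual degrees of freedom. The estimated prior degrees of freedom were infinite, so the spread of each peak was replaced by the trend over mean signal (median SD 0.14 on the log2 scale, range 0.12 to 0.20). S412A has 1 library, so its spread was assumed to be that of the other groups. P-values were adjusted over the 731 peaks by the Benjamini-Hochberg method with a threshold of 0.05. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. As that spread was pooled over peaks, p-values do not measure the spread seen at a single peak. Fold changes are ratios of geometric means, and means ± SD are on the signal scale.

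The comparisons, their tests, the alternatives and the rule for naming peaks were fixed before the data were examined. Named are, for each comparison with wild type in YPL, the 10 peaks with the largest log2 change in each direction among those past the threshold whose libraries do not overlap. Where fewer than 5 passed in a direction, the 5 with the smallest p are named as not passing, and the 10 peaks with the highest mean over all samples are named as well. Gene lists had been fixed for a test of Rph1 targets and pathways. They were not run, because the table names no genes and the gene table at hand is of build R64, whose coordinates cannot be set against those of another build, and peaks are named by position. The grouping of the outermost peak of each chromosome arm (32 peaks), its split at a width of 4 kb, and the grouping of peaks into 4 classes of wild-type signal per kb (182 or 183 peaks each) were chosen after the data were seen.

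Alternatives covered a pseudocount of 10% of the median value, leaving out the 183 peaks with the lowest mean, median-centred libraries, quantile normalization, eBayes without trend, robust eBayes, fits of only the 2 groups compared, leaving out each library in turn, and the replicate number as a block. Added after the data were seen were a plain and a crossed replicate block in fits of 2 groups, and a fit without the chromosome-end peaks. Comparisons that share the wild-type YPL libraries were set beside 100 simulated draws of unchanged groups that share 1 simulated control group. The controls were thus simulated as well, with noise independent between peaks. Replicate differences that vary with signal per kb are left out of these draws. Depth summaries and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

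The limma code was tested on simulated data with 731 peaks, 200 of them changed, in 50 simulations. With libraries shifted against each other as the replicates were, changes of log2 size 1 were recovered in 100.0% of cases for SL against YPL, 99.96% for the ppm1 deletion and 98.6% for S412A. Changes of size 0.5 were recovered in 84.8%, 78.5% and 59.2%, and of unchanged peaks 3.39%, 1.56% and 4.11% were called. These simulations gave each library a uniform shift and each peak the same noise, with an SD of 0.086. They leave out replicate differences that vary with signal per kb, as seen in these libraries. The rates therefore test the code and need not hold for the real data.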

Results

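Rph1 is a histone H3 demethylase of the JmjC family that also binds DNA through zinc fingers. The series examined where tagged Rph1 sits on chromatin in wild-type yeast growing in YPL, in wild-type yeast 1 h after the switch to SL, in cells lacking Ppm1, the methyltransferase of the phosphatase PP2A, and in cells whose Rph1 carries S412A. The table covered 731 peaks on 16 chromosomes in 7 libraries, with widths of 1083 to 10360 bp and a median of 2528 bp. Together the peaks spanned 2163 kb, 18.1% of the 11.9 Mb reaching to the last peak of each chromosome. All positions are those of the sacCer2 build named in the submitters' processing notes, and no gene was assigned to a peak.

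The share of reads in peaks was smaller in the S412A library than in each of the other 6 libraries. The share was 22.3% ± 0.892 (SD, n = 2) for wild type in YPL, 21.9% ± 3.12 (n = 2) in SL and 21.3% ± 1.88 (n = 2) for the ppm1 deletion. In the single S412A library it was 18.6% (95% Wilson interval 18.57% to 18.59%), beside the 18.1% of the span that the peaks cover, a ratio of 1.02, against 1.08 to 1.33 in the other libraries. Within the SL group the libraries stood at 24.1% and 19.7%, and within the ppm1 group at 22.6% and 20.0%. These shares rest on implied totals of 13808893 to 34820208 reads per library. What those totals count is not given, so a ratio near 1 does not show a lack of enrichment.

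Across peaks, log2 signal correlated between replicates at 0.994 for wild type in YPL, 0.984 in SL and 0.993 for the ppm1 deletion. Peaks are not independent replicates, and these values describe the libraries. Wild type in YPL correlated with the ppm1 deletion at 0.97 to 0.98, with S412A at 0.93 to 0.94, and with wild type in SL at 0.77 to 0.82. The peak with the highest mean signal lay on chromosome XII from 488758 to 490971 (57217 ± 4091 in YPL, n = 2), followed by peaks on VIII from 551814 to 562173 and on I from 138641 to 146935, with means over all libraries of 48111, 29202 and 25074. The other 7 of the 10 highest were X from 1 to 8305, IX from 1 to 8357, XIV from 628228 to 634839, VII from 478823 to 485350, XV from 1037252 to 1044014, XV from 27253 to 34173, and II from 801120 to 809688. The XII peak held 21730 per kb over all libraries, against 2463 to 3619 at the rest of the 10. Whether its DNA copy number plays a part was not tested. Of these 10, the XIV and VII peaks fell in SL (log2 -0.92 and -0.67), and none passed in the ppm1 deletion under limma, where unadjusted p-values under 0.05 numbered 45 over all 731 peaks. In S412A 4 of the 10 fell, the XII peak (-0.86), the XIV peak (-0.80), the XV peak at 1037252 (-0.79) and the VII peak (-0.62).

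The first comparison asks how Rph1 binding differs after 1 h in SL. After the switch 170 peaks rose, by a median of 1.48-fold, and 268 fell, with a median log2 change of -0.59. The split depended on the library: 112 rose and 339 fell without the first SL library, and 219 rose and 209 fell without the second. With median-centred libraries 244 rose and 300 fell, and with quantile normalization 260 rose and 296 fell. The peak on chromosome V from 339080 to 343976 rose most, from 6634 ± 154 to 32628 ± 11061 (SD, n = 2 each), a log2 change of 2.26 (SE 0.20). The peak on XIV from 499080 to 501544 fell most, from 11648 ± 744 to 4295 ± 95.3, a log2 change of -1.44 (SE 0.18). Of the 183 peaks lowest in YPL signal per kb 105 rose and 0 fell, whereas of the 183 highest 7 rose and 121 fell. The same YPL libraries set these classes and enter each log2 change. Noise in them alone therefore favours rises at low peaks and falls at high ones. The 183 lowest also had little room to fall. Their median in YPL was 1407 per kb, and the 1st percentiles over peaks in the SL libraries were 1243 and 1288.

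After the V peak, the next 9 by size of rise were X from 678334 to 683859 (log2 1.70), VIII from 25306 to 28522 (1.67), VI from 211796 to 217106 (1.65), XII from 322695 to 327429 (1.41), II from 379694 to 383475 (1.41), XVI from 127800 to 132797 (1.36), XIV from 114645 to 119291 (1.34), IV from 1452476 to 1456042 (1.33) and XII from 16404 to 20226 (1.31). In YPL 9 of these 10 peaks were among the 183 lowest in signal per kb, with 1164 to 1402, and the II peak had 1777, against a median of 2158 over all peaks. The V peak had 1355 ± 31.5 per kb there (n = 2). In SL it reached 6663 ± 2259 per kb. None of the 10 passed in the ppm1 deletion (log2 -0.00 to 0.17) or in S412A (-0.15 to 0.10). Over all 731 peaks the unadjusted p-values under 0.05 for a rise numbered 4 in the ppm1 deletion and 16 in S412A. Tested directly, the ppm1 deletion was below SL at the V peak by a log2 difference of -2.09 (limma adjusted p = 3.8e-23). As the V peak was named for its rise in the same SL libraries, this difference is no separate evidence.

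The peaks that fell most after the XIV peak were XIII from 296560 to 299369 (log2 -1.42), X from 138693 to 140653 (-1.41), X from 73244 to 75460 (-1.26), VII from 310318 to 312683 (-1.26), XV from 778118 to 781481 (-1.23), XII from 282478 to 284203 (-1.15), IV from 578835 to 581117 (-1.08), XVI from 39995 to 43601 (-1.08) and VII from 383144 to 389477 (-1.05). Of these 10 peaks, 9 were also lower in S412A and 0 in the ppm1 deletion under limma, where 41 peaks over the genome had an unadjusted p under 0.05 for a fall. Over all 731 peaks 128 were lower in S412A, 102 of them among the 183 highest in wild-type YPL signal per kb. Both comparisons share the wild-type YPL libraries, so the overlap is no measure of a shared change. The XIV peak held 9451 ± 1588 in the ppm1 deletion (n = 2) and 6716 in S412A.

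**Figure D1:**
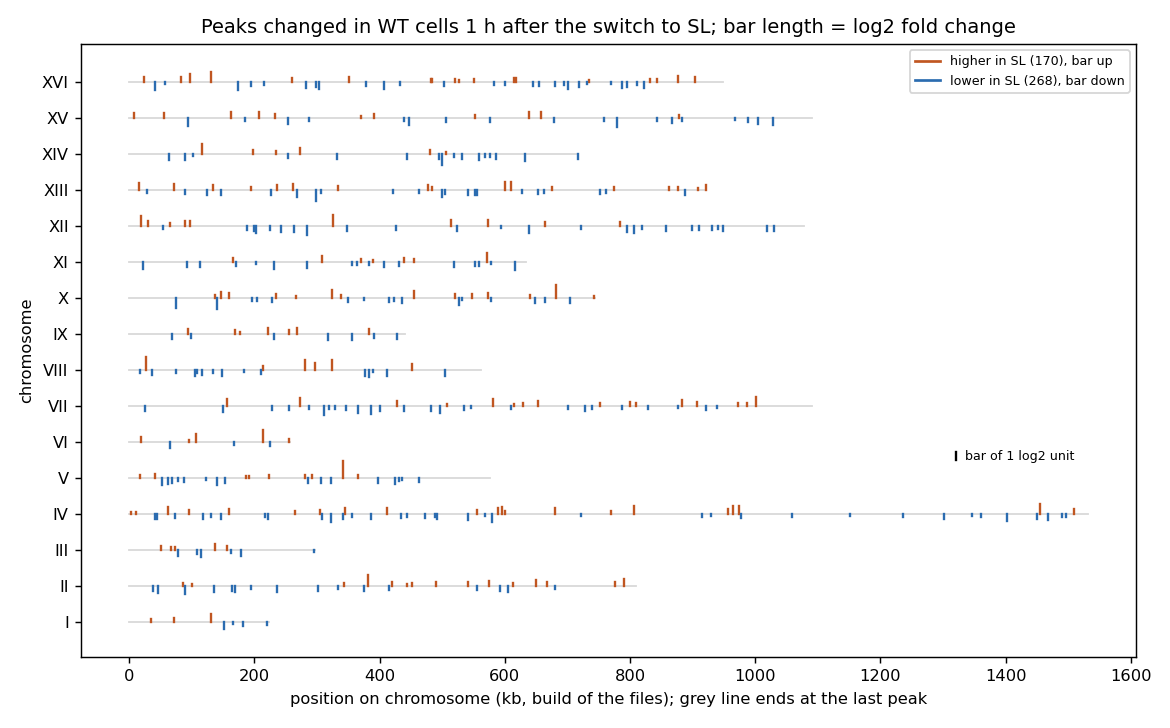
Peaks changed in wild-type cells 1 h after the switch to SL, drawn along the 16 chromosomes (x axis, position in kb), with each bar's length giving the log2 fold change. The 170 higher peaks (bars up) and the 268 lower peaks (bars down) occur on each chromosome.

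Under limma with Benjamini-Hochberg adjustment 438 of the 731 peaks passed, with an adjusted p of 3.8e-27 at the V peak and 6.7e-14 at the XIV peak. The SL libraries at the V peak held 40449 and 24806, while the test took an SE of 0.20 there from the trend over peaks. The p at the V peak therefore does not measure the spread seen at that peak. The libraries of both groups did not overlap at 577 peaks (78.9%), where chance gives 33.3% for a single peak. Peaks of a library can move together, so the excess is not a test over independent peaks. Over all peaks the median log2 change was -0.09, with library pairs from -0.28 to 0.03. An exact two-sided permutation test of the library medians gave p = 1, the smallest p that groups of 2 allow being 0.333. The count was 249 without the first wild-type YPL library and 221 without the second, and the median was -0.23 without the first SL library and 0.01 without the second.

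The second comparison sets the ppm1 deletion against wild type in YPL. Signal fell past the threshold at 9 peaks and rose at 0. The largest fall by log2 change was on chromosome XVI from 191854 to 195645, where signal went from 9350 ± 672 to 4641 ± 82.4 (SD, n = 2 each), a log2 change of -1.01 (SE 0.16, limma adjusted p = 2.6e-07). A peak on XI from 112600 to 114812 fell from 4703 ± 15.2 to 2712 ± 139 (log2 -0.80, adjusted p = 1.0e-07). A peak on XIV from 557240 to 561414 fell from 20607 ± 829 to 11633 ± 1155 (log2 -0.83, adjusted p = 0.0034).

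The other 6 were XIII from 539853 to 541349 (log2 -0.73), XVI from 678348 to 680319 (-0.72), VII from 621688 to 626965 (-0.70), IX from 426875 to 428184 (-0.56), IV from 975812 to 977992 (-0.52) and XV from 831886 to 833188 (-0.44), with adjusted p-values of 1.1e-06 to 0.0343. The 9 peaks lay on 8 chromosomes, none at a chromosome end. All 9 were also lower in S412A and 7 were also lower in SL, the exceptions in SL being the VII peak (-0.37, adjusted p = 0.085) and the XV peak (-0.17, adjusted p = 0.237). Of the 9, 7 were among the 183 peaks highest in wild-type YPL signal per kb. In that class 102 peaks fell in S412A and 121 in SL. Between S412A and the ppm1 deletion the median log2 difference at the 9 was -0.03, and limma called 0 of them in a comparison where the smallest log2 size called at any peak was 0.92. The XVI peak at 191854 stood at 4664 in S412A and at 6604 ± 503 in SL (n = 2), and SL was above the ppm1 deletion there (log2 -0.51 for ppm1 over SL, adjusted p = 0.0056).

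**Figure D2:**
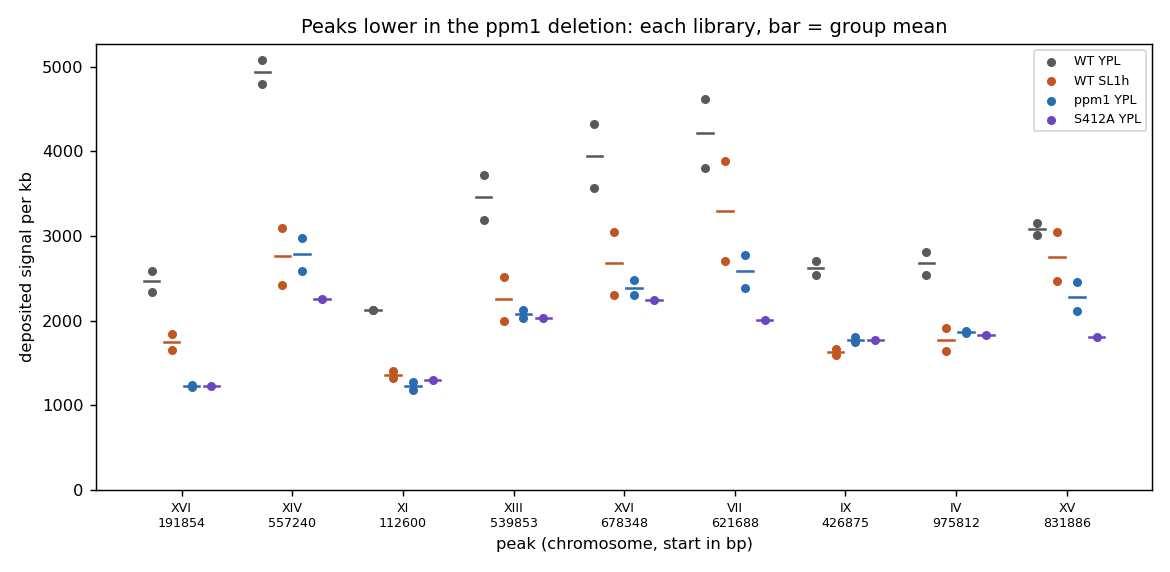
Deposited signal per kb (y axis, from 0) at the 9 peaks lower in the ppm1 deletion (x axis, chromosome and start), with a point for each library and a bar for each group mean. At the XVI peak starting at 191854 wild type in YPL averaged 2466 per kb and the ppm1 deletion 1224 per kb.

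No rise passed: limma gave 4 rises and 41 falls with an unadjusted p under 0.05. The 5 with the smallest p were IV from 555197 to 557203 (log2 0.33, adjusted p = 0.482), VII from 882015 to 884787 (0.45), VIII from 450668 to 453770 (0.37), I from 70512 to 73836 (0.36) and IV from 507087 to 510020 (0.31, adjusted p = 0.973). Libraries did not overlap at 35.4% of peaks, against 33.3% by chance, and the median log2 change was -0.01 (library pairs -0.13 to 0.08, exact permutation p = 1). Scaling changed the count and the split: with median-centred libraries 4 peaks rose and 29 fell, and with quantile normalization 13 rose and 33 fell, the 9 peaks included both times. The count was 4 or 2 without the first or second wild-type YPL library, 0 or 1 without the first or second ppm1 library, and 24 or 23 without the first or second SL library.

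The third comparison sets S412A, from a single library, against wild type in YPL. Signal was lower at most of the peaks and higher at many chromosome ends. Of the 731 peaks 635 lay below wild type, 128 of them past the threshold, and 14 rose. The largest rise was at the right end of chromosome XVI, from 942077 to 948202, from 12333 ± 342 (SD, n = 2) to 29626, a log2 change of 1.26 (SE 0.24). The largest fall was at the XIV peak from 557240 to 561414, from 20607 ± 829 to 9414, a log2 change of -1.13 (SE 0.24).

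Of the 14 rises, 13 were at the outermost peak of a chromosome arm with a width of at least 4 kb. That share depended on the scaling: with quantile normalization 68 peaks rose, 15 of them at such end peaks, so most rises then lay elsewhere. In the values as deposited there were 19 such peaks, with a median rise of 1.60-fold (log2 0.68), and 17 of them were above wild type. The largest after XVI were XII from 1 to 4032 (log2 1.03), VIII from 1 to 5000 (0.96), XVI from 1 to 6895 (0.85), VII from 1084781 to 1091069 (0.82), II from 1 to 6399 (0.76), XIII from 1 to 5871 (0.75), XII from 1071972 to 1078330 (0.71) and XV from 1083817 to 1091021 (0.69). The remaining rise, XII from 5977 to 11700 (0.71), was the next peak in from the left end of that chromosome. Exceptions among the 19 were XI from 629095 to 633301, which fell (-0.89), and II from 801120 to 809688 (-0.15, not passing). At these 19 peaks the median log2 change was 0.02 in the ppm1 deletion and 0.08 in SL, with 0 passing and 0 at an unadjusted p under 0.05 in limma for both. Chromosome ends can share repeated sequence, and the handling of reads that align to more than 1 place is not given in the sources used here. The 19 peaks may therefore not be separate observations.

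Narrow peaks at position 1 went the other way in S412A. The 4 of them, on III, IV, XI and XV, all passed as lower, with a median log2 change of -0.84. The III peak from 1 to 1616 went from 14637 ± 4431 (SD, n = 2) to 6973 (-1.04) and the IV peak from 1 to 1225 from 5969 ± 1695 (n = 2) to 3069 (-0.93). At the 4 peaks the wild-type YPL replicates differed by log2 0.51 to 0.63, while the test took an SD of 0.13 to 0.20 there. Their median was -0.42 in the ppm1 deletion, where 0 passed and limma gave an unadjusted p under 0.05 at 4 of the 13 narrow end peaks, and -0.00 in SL.

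**Figure D3:**
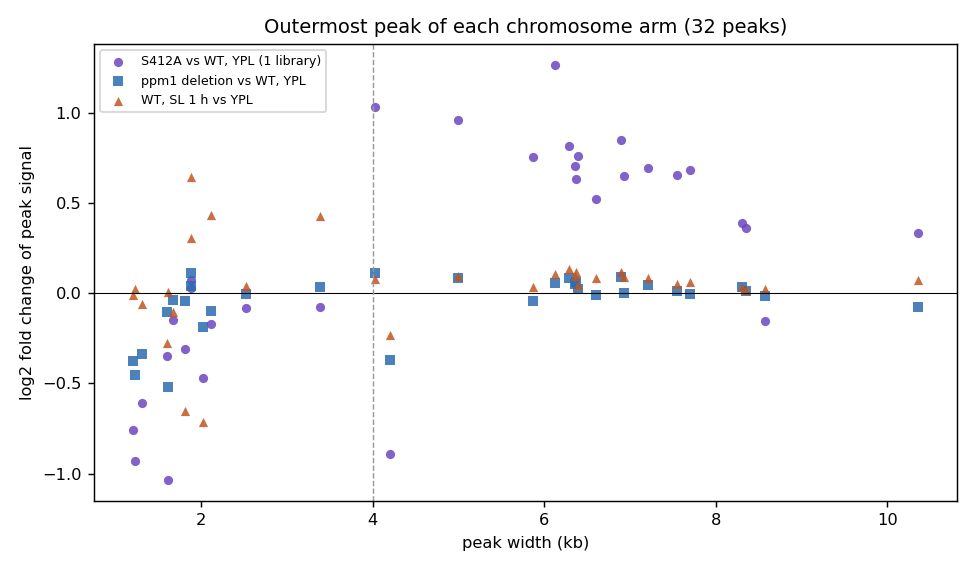
Log2 fold change against wild type in YPL (y axis) by peak width in kb (x axis) for the outermost peak of each chromosome arm, 32 peaks, in S412A, the ppm1 deletion and SL. To the right of the dashed line at 4 kb, 17 of 19 peaks lie above 0 in S412A, with a median of 0.68, while the medians of the ppm1 deletion and SL are 0.02 and 0.08.

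Falls in S412A followed the height of the peak. Of the 183 peaks lowest in wild-type signal per kb 0 fell, of the next 183 and 182 peaks 6 and 20, and of the 183 highest 102. Height and change share the wild-type YPL libraries, so noise in those libraries may add to this trend. The lowest class had a median of 1407 per kb in wild type, and the 1st percentile over peaks in S412A was 1231 per kb. The smallest log2 size called in S412A was 0.39. Peaks of that class thus had little room to fall, and the 0 falls do not show that they kept their binding. After the XIV peak the lowest internal peaks were XVI from 643761 to 647151 (-1.12), VII from 621688 to 626965 (-1.06), VII from 383144 to 389477 (-1.01), XVI from 191854 to 195645 (4664, against 9350 ± 672 in wild type, n = 2), XVI from 430771 to 434815 (-0.96) and II from 133469 to 138284 (-0.95).

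**Figure D4:**
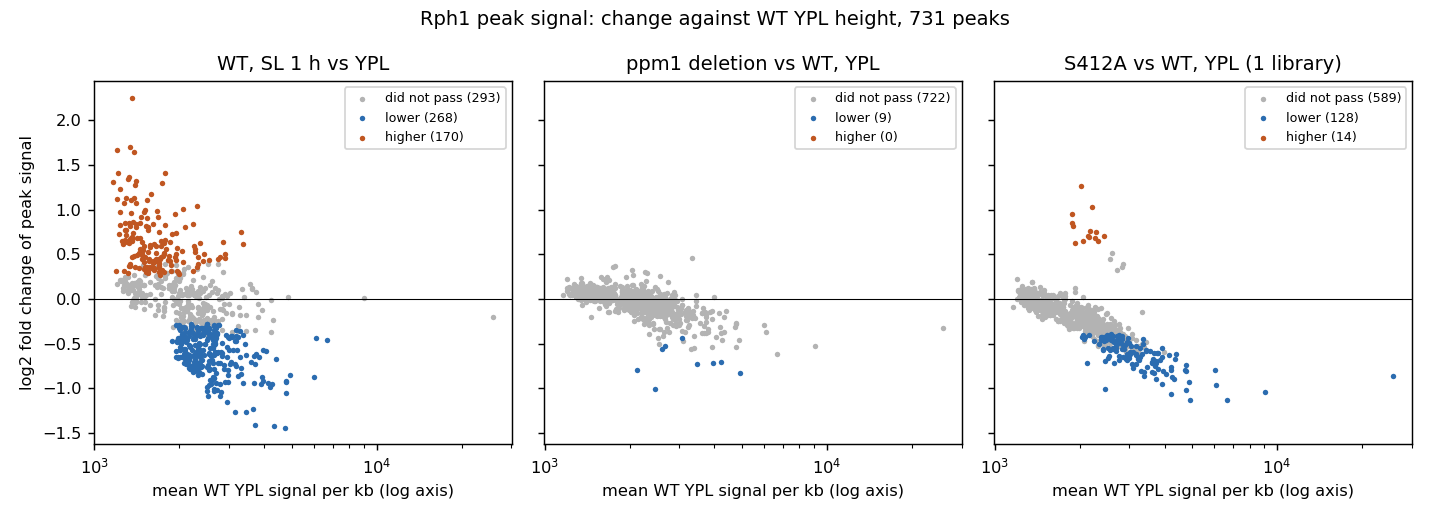
Log2 fold change of peak signal (y axis) against mean wild-type YPL signal per kb (x axis, log scale) for 731 peaks in SL, the ppm1 deletion and S412A, with peaks past the threshold in colour. The slopes on log2 signal per kb are -0.72, -0.22 and -0.44. The wild-type YPL libraries enter both axes.

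Limma gave an adjusted p of 6.0e-05 at the XVI end peak and 2.3e-04 at the XIV peak. The S412A value lay outside both wild-type values at 92.5% of peaks, where chance gives 66.7% for a single peak. A shift of the whole library moves peaks together, so the excess is no evidence beyond such a shift. The median log2 change over all peaks was -0.25 (library pairs -0.28 and -0.23), and its exact permutation p of 0.333 is the smallest that 1 library against 2 allows. Relative to that shift, with median-centred libraries, 41 peaks rose and 83 fell, and with quantile normalization 68 rose and 90 fell. The count of 142 rests on a spread taken from the other groups: it was 14 or 0 without the first or second wild-type YPL library, 2 or 0 without the first or second ppm1 library, 283 without either SL library, and 93, all falls, without the chromosome-end peaks.

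Direct tests set the departures from wild type against each other. The ppm1 deletion in YPL and wild type in SL differed at 342 peaks, 186 higher and 156 lower in the ppm1 deletion. The X peak from 138693 to 140653, named above for its fall in the same SL libraries, was higher in the ppm1 deletion by log2 1.23 (limma adjusted p = 7.1e-16). The split moved with the library left out: 278 higher and 89 lower without the first SL library, 158 and 227 without the second, 107 and 83 (190 in all) without the first ppm1 library, and 177 and 67 without the second.

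S412A exceeded the ppm1 deletion at 2 peaks, the XVI end from 942077 to 948202 (log2 1.21, limma adjusted p = 3.8e-04) and the XII end from 1 to 4032 (0.92, adjusted p = 0.0397). No peak was lower past the threshold, while limma gave 123 with an unadjusted p under 0.05, and the median log2 difference was -0.24. With median-centred libraries 19 peaks were higher and 0 lower, and with quantile normalization 10 were higher and 11 lower. The count was 0 without either wild-type YPL library, 0 without either ppm1 library, and 76 or 77 without the first or second SL library, mostly falls then (14 higher and 62 lower, 14 higher and 63 lower).

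Some peaks fell in more than 1 comparison. The 9 peaks lower in the ppm1 deletion included 7 lower in SL (3.30 for independent lists) and 9 lower in S412A (1.58 for independent lists), and S412A and SL shared 86 falls (46.9 for independent lists) and 0 rises (3.26 for independent lists), with 1 peak in opposite directions. Simulated unchanged groups that share a simulated control group gave a mean of 0.01, 0 and 0 shared calls. These draws leave out any real change and the independent lists leave out the shared controls, so the excess over either is no measure of a shared change. The log2 changes of SL and of the ppm1 deletion had a covariance of 0.0372 over peaks, against 0.0117 for the simulated unchanged groups. Their correlation was 0.43 against 0.50. The changes of S412A and of the ppm1 deletion had a covariance of 0.0322 against 0.0117, and a correlation of 0.71 against 0.40. The changes of S412A and of SL had a covariance of 0.0772 against 0.0117, and a correlation of 0.51 against 0.40. With the trend on wild-type signal per kb removed the covariances were 0.00284, 0.0113 and 0.00969. The simulated 0.0117 already includes a shared control group, with a spread taken from the fit of all groups. The difference between the 2 wild-type YPL replicates gave a smaller shared covariance of 0.00233. That value rests on 1 pair of libraries, which may be technical replicates. The wild-type YPL group of 2 cannot be split into parts with 2 libraries each, so the part due to shared controls was not measured apart. The covariance of SL with the ppm1 deletion was 0.0284 without the second wild-type YPL library, and that of S412A with the ppm1 deletion 0.0446 or 0.0244 without the first or second, none of these past the highest value of unchanged groups under that setting.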

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

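The plain and crossed blocks in fits of 2 groups and the fit without chromosome-end peaks were chosen after the results were seen. No named peak changed direction under any setting run, and the 20 named SL peaks passed under each of them. Of the 20 named S412A peaks, 13 no longer passed without the first wild-type YPL library, and 20 no longer passed without the second or without either ppm1 library. The cause of the following changes was not tested unless stated. With median-centred libraries 33 peaks changed in the ppm1 deletion and 19 between S412A and the ppm1 deletion, and with quantile normalization 46 and 21. Without the trend in eBayes the latter count was 13, and in a fit of only the 2 groups compared the ppm1 count was 21. Without chromosome-end peaks 0 peaks differed between S412A and the ppm1 deletion, both that had differed being end peaks, and S412A had 93 changed peaks, against 123 internal ones in the fit of all peaks.

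Leaving out each library in turn gave 221 to 451 changed peaks for SL, 0 to 24 for the ppm1 deletion, 0 to 283 for S412A, 190 to 385 for the ppm1 deletion against SL and 0 to 77 for S412A against the ppm1 deletion. A group left with 1 library was assumed to vary like the others. Without the first or second ppm1 library the prior degrees of freedom of the fit fell from infinite to 6.44 or 6.38. Counts can therefore move with a library outside the comparison. Median log2 changes ranged from -0.23 to 0.0098 for SL, from -0.10 to 0.07 for the ppm1 deletion and from -0.28 to -0.23 for S412A. The covariance with the ppm1 deletion ranged from 0.0239 to 0.0507 for SL and from 0.0244 to 0.0446 for S412A.

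Replicates share only a number: the correlation of same-numbered deviations was 0.14 for ppm1 with SL, -0.44 for ppm1 with wild type in YPL and -0.33 for SL with wild type in YPL. With the replicate block 419 peaks changed in SL, 8 in the ppm1 deletion and 338 between those groups. In fits of 2 groups the plain replicate block gave 285 for SL and 7 for the ppm1 deletion, and a crossed replicate block 487 and 78. No block was possible for S412A.

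Gene lists, with their alternatives, and the count tests were not run, as the table names no genes and holds scaled signal. The counting error was at most 3.15% per peak.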

Other observations

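The width and neighbour tests, and every test on the patterns below except the slope test, were chosen after the result was seen. The chromosome and slope tests were set after the changes of the peaks were seen but before their own values were. Peaks that rose in SL were wider than those that fell, with median widths of 2814 and 2203.5 bp, a difference of 610.5 bp (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give, adjusted p = 3e-05 over 3 tests). The permutation treats peaks as independent and does not measure the spread between libraries. Width divides the signal per kb, and the trend on height was not removed here. Peaks that rose also started from a lower level, with a median of 1566 signal per kb in YPL against 2512 for those that fell. The YPL signal enters both that level and the change. Rises and falls were mixed along the genome. Neighbouring peaks showed no correlation of their log2 changes (r = -0.0070 over 715 pairs, permutation p = 0.848), and the direction of change by chromosome gave a chi-square of 10.3 (permutation p = 0.809), so this test found no gathering of rises or falls on particular chromosomes.

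For the 9 peaks lower in the ppm1 deletion, a weaker immunoprecipitation in the ppm1 libraries was tested with quantile normalization, which evens out enrichment. All 9 stayed past the threshold with a median log2 change of -0.70 (SE 0.08). As the 9 were chosen as falls in these libraries, this argues only weakly against it as the whole cause. With the trend on wild-type height removed over 699 internal peaks, their median in the ppm1 deletion was smaller, -0.48. The XV peak was then at -0.28, rank 17 among the internal peaks. Deletion of whole peaks in the ppm1 strain is argued against by the remaining signal: the lowest called peak held 1224 signal per kb, 102% of the lowest value among the other peaks. That is near the floor of the table, with 2 of the 9 under its 1st percentile, and loss of part of a peak is not excluded. Extra DNA copies in the wild-type strain cannot be told apart from a change of binding, as high peaks fell in SL anyway: with the trend on wild-type height removed, the 9 peaks went both ways in SL (log2 -0.33 to 0.30, median -0.13, SD 0.22). Each test rests on the same libraries that gave the pattern, and leaving out the first or second ppm1 library left 0 or 1 peak past the threshold. The median log2 change of the 9 was then -0.74 or -0.67, against -0.72 with all libraries, while the median SE rose from 0.13 to 0.16 and the prior degrees of freedom fell from infinite to 6.44 or 6.38. An effect of the loss of Ppm1 on binding at these peaks stays open and untested.

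In S412A the rise at the 19 wide chromosome-end peaks was not removed by evening out the libraries: under quantile normalization the median log2 change was 0.65 (SD 0.38), with 17 of 19 above 0 and 15 past the threshold. These peaks were grouped after their rise in this library was seen, and quantile normalization keeps the order of peaks within a library. The result therefore argues only weakly against scaling or enrichment of that library as a whole. A bias of the library at these peaks alone would not be removed. Another copy number of chromosome-end repeats in the S412A strain is a candidate explanation that cannot be told apart from a change of binding, because no input DNA was used here. The SD of the change over the 19 peaks was 0.47, against 0.07 for the difference between the wild-type YPL replicates, but repeats may differ in number from end to end. An effect of the substitution on binding at chromosome ends remains untested with 1 library.

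Also in S412A, signal fell the more the higher the peak was in wild type. The wild-type YPL libraries enter both values, and the lowest peaks were near the floor of the table. A uniform shift from a smaller share of reads in peaks would vanish on median-centring, yet 83 peaks were lower after it, 79 of them among the 128. Weaker enrichment in 1 library may give such a slope: over internal peaks it was -0.44 on log2 signal per kb, 1.24 times the steepest slope between replicates of a group (0.36, in SL), which is too close to decide by the limit set before the replicate slopes were seen. The axes differ, as each replicate slope was taken on the mean of its own group. On the wild-type YPL height used for S412A the replicate slopes had sizes of 0.12 in wild type, 0.06 in SL and 0.13 in the ppm1 deletion, and the ratio to the steepest was 3.37. With 1 library the substitution and the library cannot be told apart.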
